A study of Mus musculus with 6 samples.

How the data were processed

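In all 3 tissue sections were measured by spatial barcoding with whole transcriptome and antibody tags, 2 of mouse spleen and 1 of a mouse mammary tumour, and each gave an RNA and an antibody sample. The deposited RNA files hold UMI counts per gene and spot, the deposited spleen antibody values are UMI counts per antibody and spot from the same files, and the deposited tumour antibody table holds counts per antibody and spot, for which it is not given in the sources used here whether they were collapsed to unique molecules. The spots are those of the filtered matrices that the authors deposited. Per the submitters' processing notes, reads were processed with Space Ranger 1.3.0 against GRCm38/mm10; further processing is not given in the sources used here. The files list 32285 genes, and 32286 in the tumour with the PyMT transgene. Counts were used as deposited, without removal of spots: 12, 19 and 15 spots of the sections had under 1000 RNA or under 200 antibody counts, and leaving them out was an alternative. Genes were taken by identifier, and where several identifiers share a symbol (38 symbols), the symbol stayed with the identifier of most counts. Spot positions were not used here, and the panels hold no isotype controls.

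RNA per spot was scaled to 10000 counts and logged. Antibody counts per spot were converted to centred log ratios (CLR, natural log with a pseudocount of 1), that is, relative to the mean log count of the panel in that spot. Each antibody was correlated (Spearman) across spots with all genes found in at least 5% of spots of the section, and its own gene was ranked among them. For fixed depth, spots were thinned to 3088 RNA and 572 antibody counts. Spots were given the class (B, T or macrophage) with the highest mean standardised score, once from 10 class antibodies and once from RNA lists; 10.1% to 21.2% of the spots of each antibody class, and 49.4% to 57.2% of each RNA class, lay within 0.25 SD of another class. Counts were summed per class and section into 6 sums, genes were filtered with filterByExpr, scaled with TMM and fitted with the quasi-likelihood test of edgeR, with the section as a block and 2 residual degrees of freedom. Contrasts were B minus T and macrophage minus the mean of B and T, two-sided, with Benjamini-Hochberg adjustment over all genes of a contrast and a threshold of 0.05. Marker lists (31 lists, 300 genes, 4 of them not in the files) were tested with camera at a preset correlation of 0.01 and with an estimated correlation, adjusted over 30 lists per contrast; milk proteins had 1 tested member and were left out there. Antibody CLR means per RNA class and section were compared with limma, on the log2 scale, with the same block. Single antibodies were compared in the spleen as sums over the 25% of spots per section with the highest and the 25% with the lowest level, also with edgeR.

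In the tumour, ratios of summed CPM between such groups of spots were taken for single genes without a prior, with exact 95% intervals from the binomial split of the counts. A prior of 1 CPM was added only for list medians and to order the genes for naming. List medians were placed among those of 10000 random lists matched in 20 expression bins. Regions were made by k-means (seed 0) on 20 principal components of 2000 variable genes. Wilson and exact Poisson intervals cover counting error only. Where a share was 0, the upper limit that 3 counts give is stated. The samples, comparisons, tests, marker lists, alternatives and the rule for named genes were fixed before the data were examined; the gene assignments of P2X7R, CD1d, Notch 4 and CD202b were added once the panel names were known, and so were the tests that the closing section names. Named genes were, per spleen contrast, the 10 largest changes in each direction among genes that passed, had the same sign in both sections and a mean of at least 20 CPM; per list, up to 4 members of highest mean level; the targets of the class antibodies; and, per single antibody, its own gene and the 5 largest ratios in each direction at 50 CPM or more. In the antibody correlations the 5 highest and 5 lowest pairs were named. Predicted, ribosomal and mitochondrial genes were counted and not named. Some genes and antibodies that this rule takes enter the counts and classes but are not reported here. Outside this rule, the following were named after their values were seen. They are the pairs of CD4, CD8 and F4/80 in the spleen, and as best genes Igkc, Hba-a2, Ccl21a and Marco in the spleen and Xbp1, Sparc, Igkc, Col1a1 and Cd74 in the tumour. They are also Hbb-bs and Car1 between the spleen sections, the leading genes of the tumour regions, PyMT by EpCAM, Pdpn and Ly6a by their antibodies, and the tumour values of Trbc2, Cd3e, Hbb-bs by CD4, Lcn2 and S100a8. The ranks of the CD11a and CD45R/B220 pairs in the tumour were named in the same way.

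Alternatives included other antibody and RNA scalings, thinning, spot filters, RLE scaling, DESeq2, stricter or no gene filters, no block, a class lead of 0.5 SD, k-means classes, 10% in place of 25% of spots on each side, other numbers of regions, and leaving out each section. The methods were tested on simulated data: with effects planted in counts drawn around the mean levels of the class sums, edgeR recovered 95% of genes at a log2 change of 0.5 with 4.41% false among calls, limma recovered 100% of shifts of 0.2 in log2 with 6 false calls over 20 runs, a planted gene ranked first in 20 of 20 correlations, and 3 of 100 random lists lay outside the random range in the tumour. The planted antibodies were the RNA of a well expressed gene plus noise, at a strength not matched to the real pairs. They do not show how weak pairs rank. The random lists held random genes compared between random spots, so they do not cover marker genes that vary together. The edgeR and limma simulations held no difference between sections and took their noise from the blocked fits themselves. They thus do not test the use of the block. Versions were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.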

Results

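RNA and antibody tags were counted on the same spots of 3 mouse tissue sections, 2 of C57BL/6J spleen and 1 of a breast tumour from an MMTV-PyMT mouse, in which polyoma middle T antigen drives mammary tumours. Each section gave 1 RNA sample and 1 antibody sample, 6 in all, over 7399 spots, each a small region that can hold several cells. Spleen section 1 had 2653 spots with 20593375 RNA counts (median 7397 per spot, range 42 to 16823) and 3847352 counts of 21 antibodies (median 1464 per spot). Spleen section 2 had 2768 spots with 22196649 RNA counts (median 7772.5) and 2902977 antibody counts (median 1046). The tumour had 1978 spots with 17215212 RNA counts (median 7641) and 86922388 counts of 32 antibodies (median 40826.5). Mitochondrial genes took 1.49% and 1.5% of the RNA counts of the spleen sections and 1.80% of those of the tumour. The tumour was a single section, so its values carry counting intervals only and no test between samples; the spleen values are means ± SD of 2 sections unless stated. Whether the spleen sections came from separate animals is not given in the labels, so the spread between them may be technical. With the section as a block, p-values of genes and antibodies measure only how alike differences between groups of spots were in these sections. The error they use is shared in part across all genes or antibodies. The SE of a gene was taken from its test statistic and carries that error, so it can lie below the spread of its own 2 sections. For Hba-a2 in macrophage spots the sections gave 1.07 and 0.997, with an SE of 0.01. The mean difference between the sections is taken out. List p-values with the preset correlation compare the genes of a list with other genes and do not measure the spread between sections. Those with an estimated correlation rest on the 2 residual degrees of freedom of the fit, so they cannot become as small.

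The spleen sections resembled each other closely as whole tissues. Over 9119 genes of at least 10 CPM (counts per 1000000) in both, the log2 levels correlated with Pearson's r = 0.995 across genes, which are not independent replicates. The SD of the log2 difference was 0.138, and no gene differed by over 2-fold. The largest differences included red cell genes: Hbb-bs, a beta globin, was at 1079 CPM in section 1 and 1764.5 CPM in section 2 (log2 difference 0.71), and Car1, the red cell carbonic anhydrase, differed by 0.69. The shares of the 21 antibodies correlated with r = 0.999.

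The first question was how far each antibody followed the RNA of its own target from spot to spot. In the spleen the closest pairs included those of B and T cells. IgD antibody followed Ighd, its heavy chain gene (ENSMUSG00000104213), with Spearman's rho = 0.256 ± 0.038, and IgM antibody followed Ighm (ENSMUSG00000076617) with 0.225 ± 0.00964. CD3 with Cd3e, a T cell receptor subunit, gave 0.159 ± 0.0075, and CD169 with Siglec1, the sialic acid receptor of metallophilic macrophages, 0.144 ± 0.00566. CD4 gave 0.137, CD8 with Cd8a 0.110 and F4/80 with Adgre1 0.0911. At the low end, CD20 antibody and Ms4a1, its gene in B cells, gave −0.0363 ± 0.0011 although Ms4a1 was found in 97.6% of spots. The other 4 lowest were CD68 (−0.0350), CD105 with Eng (−0.0338), CD11b with Itgam (−0.0240) and CD29 with Itgb1 (−0.00889, from 0.00554 in section 1 and −0.0233 in section 2). The sign of these low values depended on the scale of the antibody levels. Levels centred across spots keep the order of the raw counts, so differences in total antibody counts between spots stay in. With levels centred across spots instead of across the panel, CD105, CD11b and CD29 were positive in both sections (0.00399 and 0.0456, 0.0251 and 0.0305, and 0.0127 and 0.0195). CD20 was then at −0.000855 and 0.0288, and CD68 at −0.00981 and 0.0329.

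Ranks over all genes found in at least 5% of spots placed these values. Ighm was the 2nd best of 10254 genes for IgM antibody in section 1 and of 10288 in section 2. The best was Igkc, an antibody light chain (rho 0.26 and 0.22). Of 19 antibodies with a measurable gene, 12 had a positive rho in both sections and 8 had their own gene in the top 1% in both. When spots were thinned to the same counts, 2560 and 2484 spots and 17 antibodies with a value were left, of which 2 had their own gene in the top 1% in both. With levels centred across spots, which leave the spots' totals in, 17 were positive in both. The median rho was 0.0755 ± 0.0189, taken over 19 antibodies in section 1 and 20 in section 2, where EpCAM also had a value. After thinning it was 0.0425, over 17. The 19 values correlated between the sections with r = 0.968 across antibodies; rho across spots is descriptive, since spots are not replicates.

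**Figure D1:**
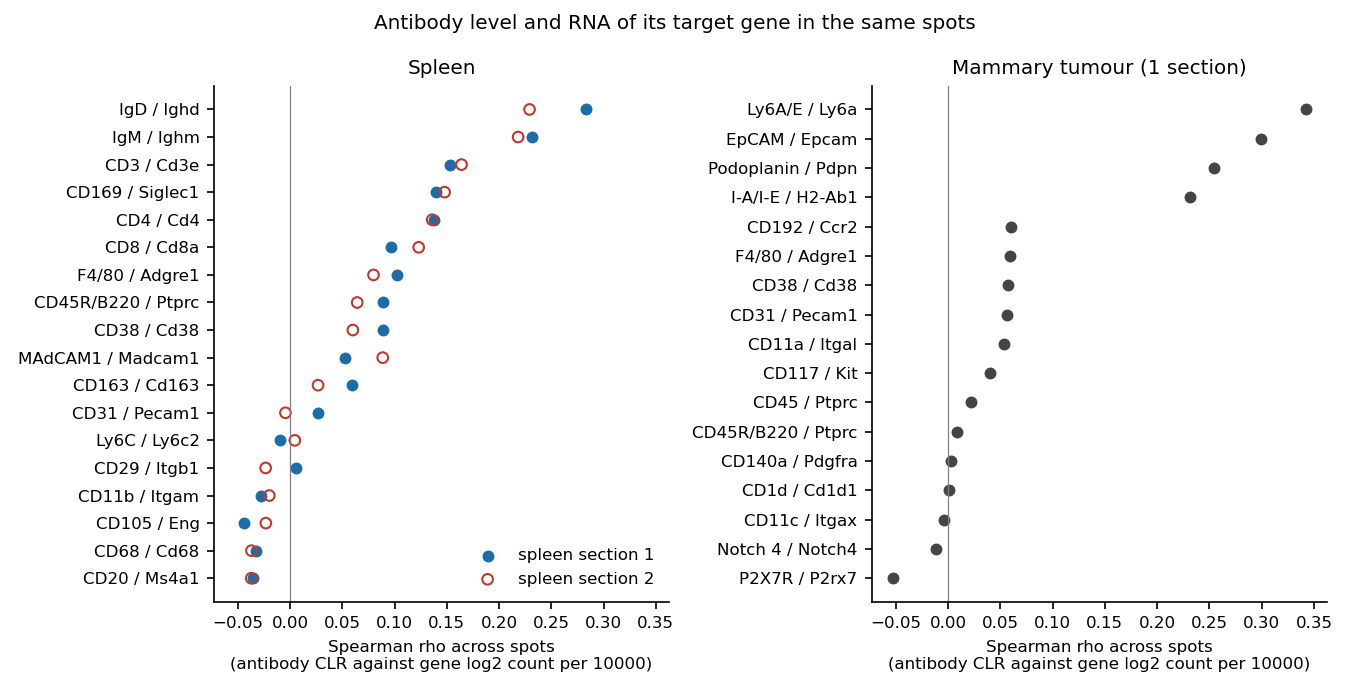
Spearman's rho across spots (x axis, no unit) between each antibody and the RNA of its own gene, for 18 of the 19 pairs in the spleen (left; filled blue, section 1; open red, section 2) and 17 in the tumour (right). The spleen sections lie close together for most pairs, from IgD (0.283 and 0.229) to CD20 (−0.0355 and −0.0371), and Ly6A/E has the highest value of the tumour (0.343).

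In neither spleen section was an antibody's own gene its best one. For F4/80 antibody the best was Hba-a2, an alpha globin (ENSMUSG00000069917), with rho 0.848 and 0.827. For CD3, CD4 and CD8 antibodies it was Ccl21a, a chemokine of T zone stroma (ENSMUSG00000094686), with 0.39 and 0.46, 0.40 and 0.46, and 0.28 and 0.31. For CD169 antibody it was Marco, a scavenger receptor of marginal zone macrophages (ENSMUSG00000026390), with 0.30 in each section. These correlations have no error beyond the pair of sections.

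Spots were then placed in a B, T or macrophage class, once by antibodies (among them CD20, CD45R/B220 and IgD for B, CD3, CD4 and CD8 for T, and F4/80, CD163 and CD68 for macrophages) and once by RNA marker lists, to ask how often both gave the same class. They did so in 56.5% ± 0.626 of spots (57.0% and 56.1%, where chance gives 33.6%), with Cohen's kappa of 0.352 and 0.338. Of the antibody B spots, 66.0% and 62.6% were also B by RNA; of the T spots 61.2% and 58.0% were T, and of the macrophage spots 49.3% and 50.3% were macrophage. When both classes had to lead the next class by at least 0.5 SD, the share was 87.4% ± 2.38, over 406 and 357 spots. The antibody classes held 836, 534 and 1283 spots (B, T and macrophage) in section 1 and 908, 631 and 1229 in section 2. Their depth differed: the median RNA count per spot was 8726 and 8803 in B spots, 10054.5 and 9729 in T spots, and 6447 and 6394 in macrophage spots.

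The next question was which RNAs differed between spots that antibodies called B and T. T spots had more RNA of T cell genes: Cd8b1, the beta chain of CD8 (ENSMUSG00000053044), was at 93.5 ± 4.32 CPM in B and 166 ± 3.03 CPM in T spots (log2 difference B minus T −0.82 ± 0.05 SE, adjusted p = 3.1e-24). Cd3g (ENSMUSG00000002033) differed by −0.75 ± 0.09, Thy1 by −0.64 ± 0.04, and Cd27, a co-stimulatory receptor, by −0.64 ± 0.05. Ccl22, a chemokine made by dendritic cells (ENSMUSG00000031779), was lower in B spots by −0.80 ± 0.09 (adjusted p = 1.7e-10), and Foxp3, the regulator of regulatory T cells (ENSMUSG00000039521), by −0.64 ± 0.11 (adjusted p = 1.0e-05). B spots had more RNA of Cr2, a complement receptor of B cells and follicular dendritic cells (ENSMUSG00000026616), at 462 ± 9.05 against 339 ± 9.86 CPM (0.45 ± 0.03, adjusted p = 1.1e-21). They also had more Ebf1, a B cell transcription factor (ENSMUSG00000057098; 0.46 ± 0.05, adjusted p = 1.4e-12), and Cxcl13, the chemokine of follicles (ENSMUSG00000023078; 0.40 ± 0.05, adjusted p = 2.2e-10). Siglec1 of metallophilic macrophages (ENSMUSG00000027322) was also higher in B spots, at 71.8 ± 2.94 against 51.6 ± 1.35 CPM (0.48 ± 0.07, adjusted p = 6.0e-07).

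The other named genes higher in B spots were Il9r (0.62 ± 0.12), Mbd4 (0.49 ± 0.12), Pxdc1 and Extl1 (each 0.40), Myof (0.40 ± 0.11) and Sulf1 (0.39 ± 0.09). Within single sections Myof ranged from 0.24 to 0.50, Il9r from 0.47 to 0.73 and Mbd4 from 0.37 to 0.58. Those lower in B spots were Dcn, a matrix proteoglycan (−0.73 ± 0.09), Csf2rb2 (−0.67), Klk8 (−0.65) and Arhgap22 (−0.65). The genes of the class antibodies moved with them: Cd3e (−0.59 ± 0.05), Cd8a (−0.59) and Cd4 (−0.43) were lower, and Ms4a1 (0.29 ± 0.02) and Ighd (0.18) higher in B spots. Ptprc, which encodes B220 among other forms, was at −0.04 (adjusted p = 0.315). Of 13290 genes tested on the 6 class sums with the section as a block, 206 were higher and 306 lower in B spots, all with the same sign in both sections. Without the block 49 genes passed, 9 higher and 40 lower, and with DESeq2 96, 34 higher and 62 lower. DESeq2 gave an adjusted p-value to 5700 genes only, so a gene that did not pass there may have had none. Csf2rb2, Extl1, Foxp3, Il9r, Klk8, Mbd4, Myof and Sulf1 did not pass in either, and Cxcl13, Dcn and Ighd did not pass without the block. Of the called genes 13 were ribosomal, 8 of them lower in B spots, and 6 were mitochondrial, all lower. Whether RNA quality differed between the classes was not tested.

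By marker list, all 16 T cell genes were lower in B spots (median −0.55, adjusted p = 3.8e-112, and 0.0346 with an estimated correlation) and all 13 B cell genes higher (median 0.24, adjusted p = 1.7e-83, and 0.0346 with an estimated correlation). Among these were Cd79a (0.21 ± 0.02) and Cd79b (0.25 ± 0.02), the signalling chains of the B cell receptor. Both counts were the same adjusted over the list alone. Without the block 14 of the T cell and 4 of the B cell genes passed, and with DESeq2 13 and 9. Of 30 lists tested, 16 passed with the preset correlation and these 2 also with the estimated one. T zone stroma and homing fell in B spots with 4 of 8 members, also 4 adjusted over the list alone (median −0.28, adjusted p = 0.0882 with an estimated correlation), led by Ccl21a at 2836 against 4111 CPM (−0.54 ± 0.02, adjusted p = 1.7e-46). Dendritic cell genes fell with 5 of 10 members, 8 adjusted over the list alone (median −0.26, adjusted p = 0.168 with an estimated correlation), such as Itgax (−0.35) and Fscn1 (−0.40). Regulatory T cell genes fell with 3 of 6, 5 adjusted over the list alone (median −0.33, adjusted p = 0.150 with an estimated correlation), among them Tnfrsf18 (−0.34, and −0.46 to −0.21 within single sections). Without the block 3 of the T zone stroma genes, 1 dendritic cell gene and 0 regulatory T cell genes passed.

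Lists of the marginal zone and the follicle rose in B spots. Marginal zone B cell genes rose with 4 of 6 members, also 4 adjusted over the list alone (median 0.22, adjusted p = 0.150 with an estimated correlation), including S1pr3 (0.26) and Dtx1 (0.17). Marginal zone macrophage genes rose with 3 of 6 (3 higher and 1 lower adjusted over the list alone; median 0.22, adjusted p = 0.136 with an estimated correlation), including Marco (0.32 ± 0.02) and Timd4 (0.30 ± 0.06). Follicular dendritic cell and stroma genes rose with 5 of 8, 6 adjusted over the list alone (median 0.16, adjusted p = 0.136 with an estimated correlation). Class II antigen presentation rose with 6 of 9, 7 adjusted over the list alone (median 0.13, adjusted p = 0.121 with an estimated correlation), as for H2-DMb2 (0.21) and H2-Aa (0.06). Without the block 1 marginal zone B cell gene and 1 marginal zone macrophage gene passed, and 0 genes of the follicle and class II lists.

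Further lists passed with few members, of which 1 gene, in the cytotoxic T cell list, passed without the block. Fibroblast and matrix genes fell in B spots with 5 of 12, 6 adjusted over the list alone (median −0.19, adjusted p = 0.168 with an estimated correlation), such as Col1a1 (−0.24) and Sparc (−0.17). Cytotoxic T cell genes fell with 1 of 7, Ccl5 (−0.59), and 2 adjusted over the list alone (median −0.32, adjusted p = 0.223 with an estimated correlation). Natural killer genes fell with 2 of 9, also 2 adjusted over the list alone (median −0.18, adjusted p = 0.223 with an estimated correlation). Smooth muscle genes fell with 1 of 8, Tagln (−0.38), also 1 adjusted over the list alone (median −0.08, adjusted p = 0.285 with an estimated correlation), and interferon response genes with 2 of 9, 4 adjusted over the list alone (median −0.11, adjusted p = 0.225 with an estimated correlation), such as Bst2 (−0.12). Monocyte genes fell as a list with 3 of 8 lower and 1 higher, 4 lower and 1 higher adjusted over the list alone (median −0.16, adjusted p = 0.20 with an estimated correlation), where Ly6c2 (−0.38) and Fn1 (−0.30) were lower and Plac8 (0.15) higher. Within single sections Fn1 ranged from −0.42 to −0.16 and Ly6c2 from −0.50 to −0.26. Erythroid genes rose with 2 of 11, Hba-a2 (0.08) and Hbb-bt (0.09), and 4 adjusted over the list alone (median 0.03, adjusted p = 0.223 with an estimated correlation and 0.304 without the block). Among lists that did not pass, median, mean and test differed in sign for red pulp macrophages, cell cycle, iron handling, mammary basal and hypoxia genes, all with medians within 0.04 of 0.

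Macrophage spots were compared with the mean of B and T spots to ask what marks the red pulp, where F4/80, CD163 and CD68 are carried by macrophages. Red cell genes led. Hba-a2 was at 64578 CPM in macrophage spots against 32470 in B and 30665 in T spots (log2 difference 1.03 ± 0.01 SE, adjusted p = 1.2e-82). Alas2, the first enzyme of haem synthesis in red cell precursors (ENSMUSG00000025270), was at 193 against 85.3 and 84.6 CPM (1.19 ± 0.04, adjusted p = 1.5e-43), and the globins Hbb-bt (ENSMUSG00000073940) and Hba-a1 (ENSMUSG00000069919) differed by 1.17 ± 0.02 and 1.16 ± 0.02. Nfe2, an erythroid and megakaryocyte transcription factor (0.94 ± 0.07), Add2, a membrane skeleton protein (0.93), Ctse (0.91), Slc43a1 (0.93), Kif3a (1.1 ± 0.08) and Ube2c, a mitotic ubiquitin enzyme (0.94 ± 0.05), were also higher. Lower in macrophage spots were Tnpo3 (−0.70 ± 0.07), Pabpn1 (−0.63 ± 0.05), Mrpl9 (−0.61), Glg1 (−0.59), Ly9, a lymphocyte surface receptor (−0.52), Mrpl52 (−0.51), Lta4h (−0.49), Cnn2 and Pfn1 of the actin skeleton (each −0.49) and Pdcd2 (−0.48).

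The antibody targets Adgre1 (0.38 ± 0.04; 152 against 117 and 118 CPM) and Cd163 (0.83 ± 0.16; 11.3 against 5.57 and 7.11 CPM) were higher in macrophage spots, and Cd68 was at −0.09 (adjusted p = 0.472). Cd3e (−0.28), Cd4 (−0.21), Cd8a (−0.14), Ptprc (−0.09), Ms4a1 (−0.05) and Ighd (−0.05) were lower. Cd8a ranged from −0.20 to −0.09 within single sections. In all 1048 genes were higher and 971 lower, 2017 of these 2019 with the same sign in both sections. The count was 409 without the block (222 higher and 187 lower) and 421 with DESeq2 (220 and 201), which gave 9724 genes an adjusted p-value. Cd4, Cd8a, Ighd, Ms4a1 and Ptprc passed in neither, Adgre1 did not pass without the block, and Cd163 and Pdcd2 did not pass with DESeq2. Of the called genes 77 were ribosomal, 75 of them lower in macrophage spots, and 11 were mitochondrial, all lower, in the class with the lowest RNA depth.

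All 11 erythroid genes rose in macrophage spots, also 11 adjusted over the list alone (median 0.83, adjusted p = 0.0176 with an estimated correlation), the only list of the 14 that passed with the preset correlation to pass with the estimated one. Red pulp macrophage genes rose with 10 of 12, also 10 adjusted over the list alone (median 0.32, adjusted p = 3.8e-16, and 0.175 with an estimated correlation), among them Slc40a1, the iron exporter (ENSMUSG00000025993; 0.43 ± 0.03), Vcam1, an adhesion molecule (ENSMUSG00000027962; 0.33 ± 0.02), and the complement gene C1qa (0.30 ± 0.03). Iron and haem handling rose as a list with 7 of 11 higher and 3 lower, the same adjusted over the list alone (median 0.27, adjusted p = 0.175 with an estimated correlation); Hebp1 (0.37) and Trf (0.19) were higher and Fth1, ferritin heavy chain, lower (−0.10). Megakaryocyte and platelet genes rose with 6 of 7, all 7 adjusted over the list alone (median 0.81, adjusted p = 0.201 with an estimated correlation), such as Ppbp (0.81 ± 0.07) and Pf4 (0.68). Neutrophil genes rose with 7 of 9, 8 adjusted over the list alone (median 0.71, adjusted p = 0.269 with an estimated correlation), such as the granule gene Camp (0.76 ± 0.07) and S100a9 (0.74 ± 0.10). Cell cycle genes rose with 6 of 11, also 6 adjusted over the list alone (median 0.39, adjusted p = 0.175 with an estimated correlation), such as Cdk1 (0.45) and Birc5 (0.44). Without the block 10 erythroid, 6 red pulp macrophage, 5 iron handling, 4 megakaryocyte, 4 neutrophil and 5 cell cycle genes passed, all higher. With DESeq2 the numbers higher were 11, 7, 5, 1, 4 and 4 in the same order, and 1 iron handling gene was lower.

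Endothelial genes rose in macrophage spots with 5 of 11, also 5 adjusted over the list alone (median 0.17, adjusted p = 0.269 with an estimated correlation), including Stab2 of sinus endothelium (0.37). Plasma cell genes rose as a list with 3 higher and 1 lower of 11, 4 and 2 adjusted over the list alone (median 0.13, adjusted p = 0.175 with an estimated correlation and 0.0508 without the block), including Jchain (0.31), Igha (0.28) and Igkc (0.13). The interferon response list passed upwards with 4 higher and 1 lower of 9, 4 and 3 adjusted over the list alone (median 0.03, mean 0.13, adjusted p = 0.175 with an estimated correlation), where Bst2 was at 0.08 (0.04 and 0.11 within single sections). Lymphoid lists fell: T cell genes with 12 of 16, 13 adjusted over the list alone (median −0.24, adjusted p = 0.175 with an estimated correlation). T zone stroma fell with 5 of 8 lower and 1 higher, the same adjusted over the list alone (median −0.28, adjusted p = 0.175 with an estimated correlation), where Ccl21a was at −0.36 ± 0.01 and Klf2 at 0.15. Class II presentation fell with 7 of 9 lower and 1 higher, 8 and 1 adjusted over the list alone (median −0.11, adjusted p = 0.175 with an estimated correlation). Follicular dendritic cell and stroma genes fell with 5 of 8 lower and 1 higher, Coch (0.33), the same adjusted over the list alone (median −0.20, adjusted p = 0.269 with an estimated correlation). B cell genes fell with 7 of 13, 8 adjusted over the list alone (median −0.05, adjusted p = 0.242 with an estimated correlation). Median and test differed in sign for mammary luminal and adipocyte genes, which did not pass, and regulatory T cell genes passed as a list only without the block (adjusted p = 0.0283). Among single genes without the block, 1 endothelial, 2 plasma cell and 2 interferon response genes passed as higher. As lower, 7 T cell, 3 T zone stroma, 1 class II, 1 follicle and 2 B cell genes did.

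**Figure D2:**
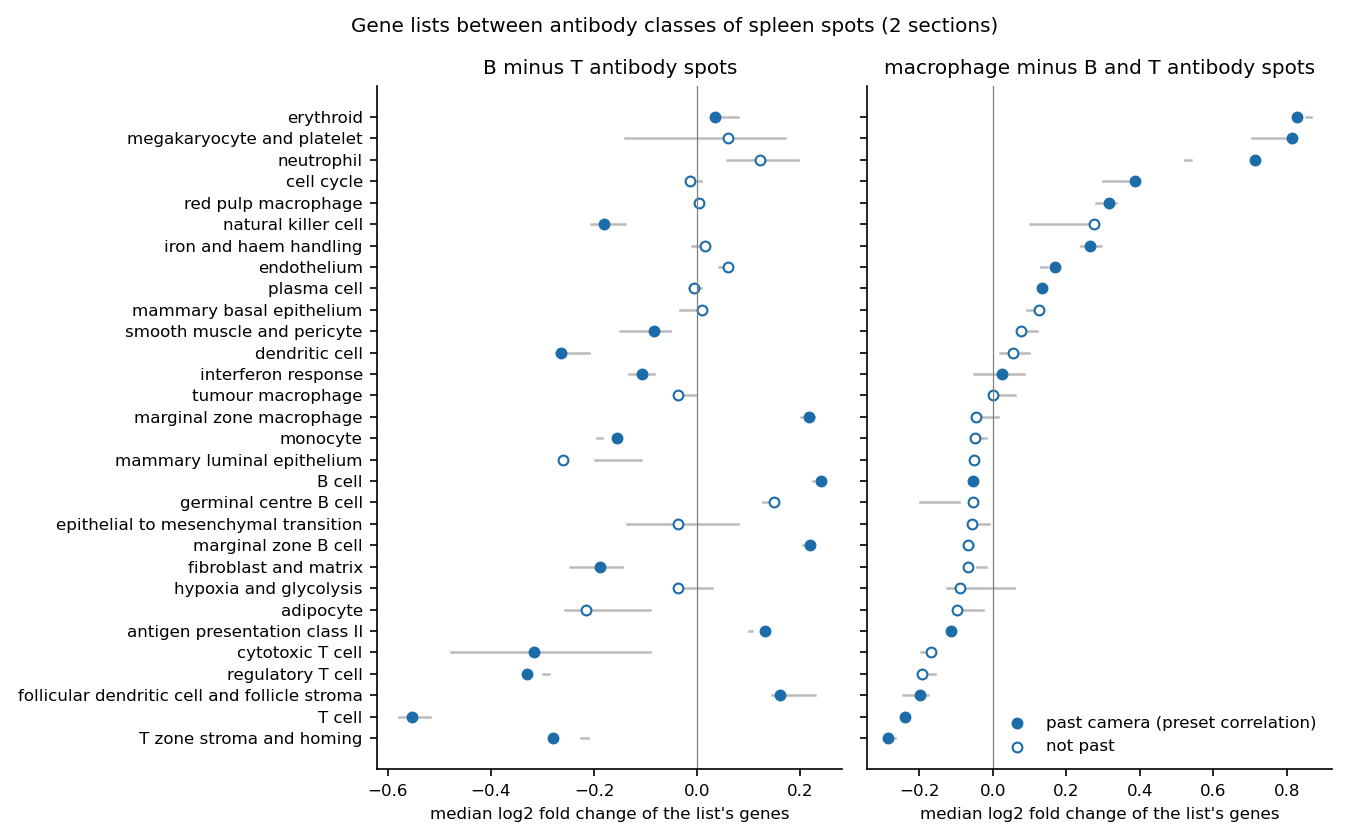
Median log2 fold change (x axis) of the genes of each marker list in the spleen, for B minus T antibody spots (left) and macrophage minus the mean of B and T antibody spots (right); filled points passed camera with the preset correlation, open points did not, and grey lines span the medians of the 2 sections on log2(CPM + 1), which can lie beside the fitted median. The T cell list lies lowest on the left (−0.55) and the erythroid list highest on the right (0.83).

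The same question was asked from the RNA side, with spots classed by RNA lists and antibody levels compared relative to the mean of the panel, so that a rise of some antibodies lowers the others. RNA T spots had more CD3 antibody than RNA B spots (log2 difference B minus T −0.54 ± 0.015 SE, adjusted p = 4.5e-06), more CD8 (−0.35 ± 0.017) and more CD4 (−0.35 ± 0.016). RNA B spots had more CD169 (0.47 ± 0.027, adjusted p = 3.3e-05), IgD (0.34 ± 0.017, adjusted p = 2.2e-05), CD45R/B220 (0.34), CD38 (0.22), IgM (0.15) and MAdCAM1 (0.10), while CD20 was at −0.05 (adjusted p = 0.0928). CD68 (−0.23), F4/80 (−0.15), CD163 (−0.15), CD29 (−0.06) and CD11b (−0.06) were lower in B spots. In all 15 of 21 antibodies passed, and 10 without the block, which lost CD11b, CD163, CD29, F4/80 and MAdCAM1. With a class lead of at least 0.5 SD, F4/80 stood at 0.01 (adjusted p = 0.777) and CD163 at −0.03 (adjusted p = 0.622), and CD11b and CD29 did not pass either.

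RNA macrophage spots had more F4/80 (0.72 ± 0.019, adjusted p = 1.9e-06) and CD163 (0.63 ± 0.013, adjusted p = 9.9e-07), more CD68 (0.40), CD29 (0.28), CD105 (0.11) and CD11b (0.06). The antibodies they had less of included CD169 (−0.35), CD4 (−0.34), CD3 (−0.32), CD45R/B220 (−0.31), IgD (−0.30), CD8 (−0.10), MAdCAM1 (−0.09) and CD38 (−0.07). Of 21 antibodies 15 passed, and 12 without the block, which lost CD11b, CD38 and MAdCAM1; CD38, CD8 and MAdCAM1 did not pass with counts per 10000.

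For single antibodies, the 25% of spots of each spleen section with the highest level were compared with the 25% with the lowest. Own genes that passed were all higher where the antibody was high, among them Cd163 (1.13 ± 0.21), Siglec1 (0.64), Cd3e (0.58), Adgre1 (0.50 ± 0.05), Cd8a (0.50), Cd4 (0.43), Madcam1 (0.31), Ighm (0.29), Ighd (0.22), Cd38 (0.16) and Ptprc (0.08). In all 12 of 20 passed, and the rest, such as Cd68 (0.10) and Ms4a1 (−0.05), did not pass. CD169-high spots had more Marco (0.54), Timd4 (0.53), Ly86 (0.57) and Ebf1 (0.53), CD3-high spots more Cd8b1 (0.79), Thy1 (0.67) and Ccr7, a homing receptor of T zones (0.64), and IgM-high spots more Ighg3 (0.41), Jchain (0.35) and Mzb1 (0.32). Among genes of at least 50 CPM the largest changes by CD3 and CD169 went down and were in red cell genes, Hbb-bt (−1.04 for each) and Alas2 (−0.95 and −1.05). F4/80 gave 2209 genes and CD20 19, with a median of 592 over the 21 antibodies. These fits had 1 residual degree of freedom; without the block the median was 103, and genes that did not pass included Cd38, Ptprc, Ighm and Madcam1 (adjusted p = 0.750, 0.723, 0.0573 and 1.00). The named genes of IgM-high spots did not pass without it either, namely Ighg3 (adjusted p = 1.00), Jchain (0.0901) and Mzb1 (0.269), while those of CD169-high and CD3-high spots passed. For IgM 1 gene was then higher and 1 lower. With 10% of spots on each side Ptprc did not pass.

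In the tumour the transgene itself was measured: PyMT gave 1755 counts in 998 of 1978 spots, a share of 50.5% (Wilson 95% interval 48.3 to 52.7). Of 17 antibodies with a measurable gene the closest pairs were Ly6A/E with Ly6a (rho 0.343, the best of 11324 genes), EpCAM with Epcam, an epithelial adhesion molecule (0.299), Podoplanin with Pdpn (0.254), I-A/I-E, the class II molecules, with H2-Ab1 (0.232), and CD192 with Ccr2 (0.0604). The lowest were P2X7R (−0.0529), Notch 4 (−0.0118), CD11c (−0.00342), CD1d (0.000499) and CD140a (0.00267). The median was 0.0534, 14 values were positive and 4 genes ranked in the top 1%. A positive value did not by itself set the own gene apart. The median pair, CD11a with Itgal, ranked 5353 of 11324 genes, and CD45R/B220 with Ptprc (0.00877) ranked 10371. With levels centred across spots instead of across the panel, which leaves the spots' total antibody counts in, the median was 0.176. The best gene was Xbp1 for EpCAM (0.51), Sparc for Podoplanin (0.48), Igkc for CD11b (0.48), Col1a1 for F4/80 (0.35) and Cd74, the class II invariant chain, for I-A/I-E (0.33). Tumour antibodies rose and fell together in raw counts, with a median pair rho of 0.948 against 0.379 and 0.447 in the spleen. IgD and Ly6G antibodies made up 2.47% and 1.31% of tumour antibody counts, although Ighd was counted in 0.303% of spots and Ly6g in 0, which allows a count in up to 0.152% of spots. These shares limit spots with a count of the RNA, not spots that express it at a lower level.

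Tumour spots with the most and the least of 8 lineage antibodies (494 spots on each side) were compared by the ratio of their summed RNA. The levels were relative to the panel, and for some antibodies the sides differed more in total antibody counts than in the antibody itself. EpCAM counts per spot had a median of 2471 on the high and 2169 on the low side, where total antibody counts were 29096 and 60387.5. For CD45 these were 3145.5 and 2943, with totals of 34472.5 and 42057.5. EpCAM-high spots had more Epcam, at 1531 against 1145 CPM (log2 ratio 0.42, 95% interval 0.37 to 0.47), more Car6, a secreted carbonic anhydrase (ENSMUSG00000028972; 2.44, 2.32 to 2.57), Scgb2b27 (2.00), Atp2a3, a calcium pump (1.65, 1.59 to 1.72), and Scgb1b27 (1.46). They also had more PyMT, at 129 against 66.4 CPM (0.96, 0.75 to 1.17). They had less Hba-a2 (−4.20, −4.44 to −3.98), Hba-a1 (−4.07), Hbb-bs (−3.39), Cfd, the adipocyte complement factor (−3.87), and Jchain (−2.44). Luminal epithelium (median 0.46) and cell cycle genes (0.36) lay above the 97.5 percentile of expression-matched random lists, and 20 lists lay below the 2.5 percentile, including erythroid (−3.26), adipocyte (−1.51), basal epithelium (−1.29) and fibroblast genes (−1.24).

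CD11b-high spots had the mirror pattern, with more Hba-a2 (4.46, 4.25 to 4.67), Hba-a1 (4.15), Hbb-bs (3.38), Cfd (3.94, 3.46 to 4.47) and Cilp, a matrix protein (3.28), more Itgam (2.09, 0.90 to 3.44, from 26 against 8 counts). They had less Atp2a3 (−1.81), Eno1 (−1.55), Car6 (−1.54), Csn1s1, a casein (−1.48), and PyMT, at 46.2 against 125 CPM (−1.44, −1.70 to −1.18). Of 31 lists 19 lay above the random range, among them fibroblast (1.47), plasma cell (0.99), interferon response (0.95), monocyte (0.89) and class II genes (0.88). F4/80-high spots had more Adgre1 (0.94, 0.48 to 1.41), Col1a1 (ENSMUSG00000001506; 2.13, 1.97 to 2.30), Cfd (2.67, 2.28 to 3.09) and the antibody genes Igha (2.29), Jchain (2.29) and Igkc (2.27). They had less PyMT (−0.82), Csn1s1 (−0.95), Eno1 (−0.81), Vegfa (−0.78) and Ntrk2 (−0.75). The fibroblast list was at 1.17, monocyte at 0.97, class II at 0.87 and tumour macrophage at 0.63, all above the random range, while hypoxia (−0.27) and cell cycle genes (−0.20) were below it. Median RNA counts per spot were 5748 in CD11b-high against 8779 in CD11b-low spots, and 5306.5 against 8970 for F4/80.

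I-A/I-E-high spots had more H2-Ab1, at 688 against 381 CPM (0.85, 0.76 to 0.95), Jchain (1.3), Igkc (1.2), Igha (1.18), Col1a1 (1.02) and Col3a1 (1.00). They had less Hba-a2 (−3.27, −3.45 to −3.09), Hba-a1 (−2.14), Hbb-bs (−1.88), Acta1, skeletal muscle actin (−1.86), and Fcgbp (−1.22). Class II (0.85), monocyte (0.68) and T cell genes (0.49) were above the random range, and erythroid (−1.83) and hypoxia genes (−0.39) below it. CD45-high spots had more Ptprc (0.67, 0.15 to 1.2), Igkc (1.16, 1.04 to 1.28), Jchain (1.16), Igha (1.13), Scgb1b27 (0.80) and Car6 (0.76), and less Twist1, a regulator of mesenchymal fate (ENSMUSG00000035799; −1.01, −1.34 to −0.69). For CD31, CD4 and CD140a the intervals of the own genes included 0: Pecam1 was at 0.04 (−0.38 to 0.46), Cd4 at −0.42 (−1.76 to 0.98, from 13 and 9 counts on the high and low side) and Pdgfra at 0.26 (−0.29 to 0.81). With 10% in place of 25% of spots on each side Pecam1 was at 0.87 (0.09 to 1.71), Cd4 at 0.32 (−1.74 to 2.87) and Ptprc by CD45 at 0.33 (−0.67 to 1.3). Hba-a2 was higher on the high side of CD31, CD4 and CD140a (0.93, 1.33 and 2.56). Over the 8 antibodies, with 31 lists each, 103 pairs of an antibody and a list lay outside the random range. Of these, 70 were outside on the same side with 10% of spots.

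**Figure D3:**
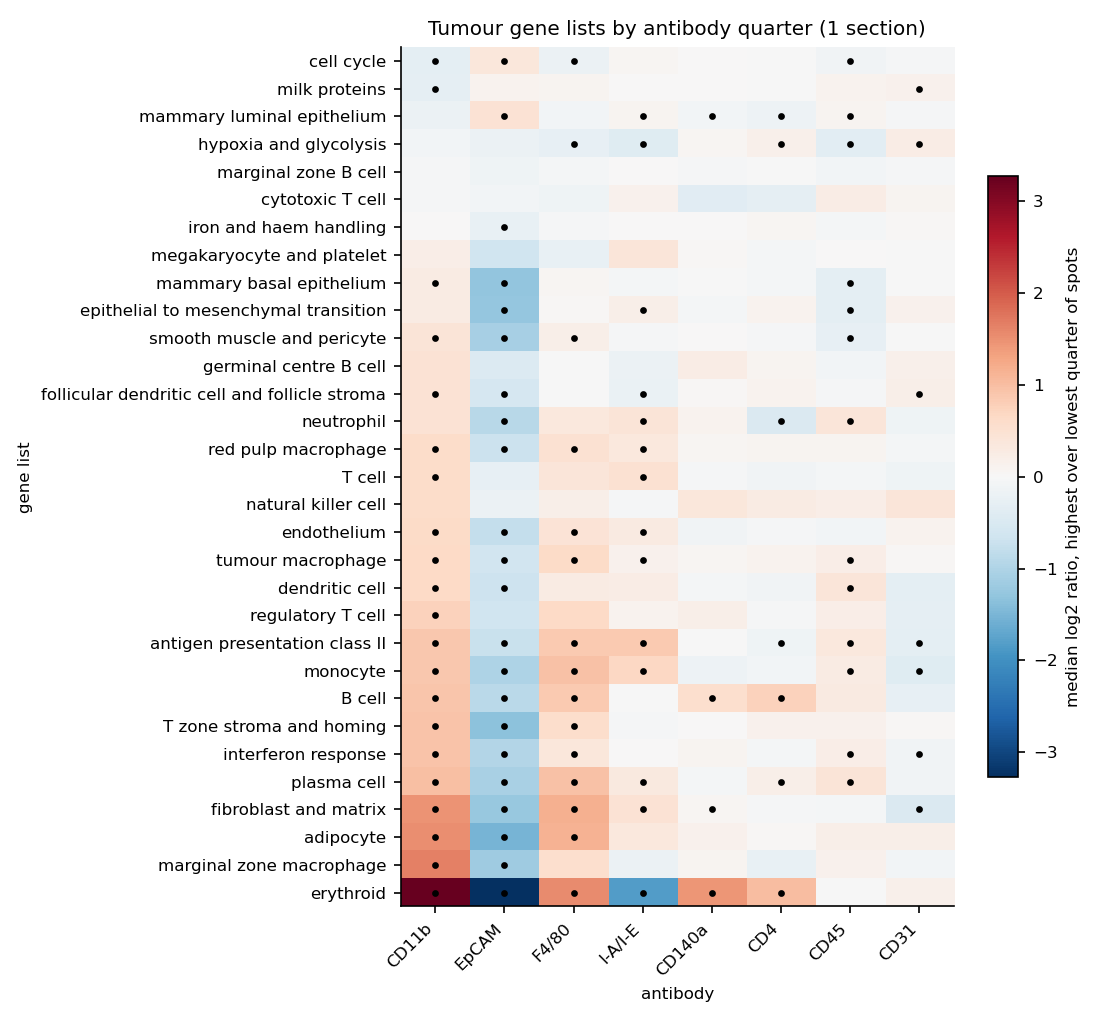
Median log2 ratio of RNA levels (colour) in the 25% of tumour spots with the highest over the 25% with the lowest level, for 8 antibodies (columns) and 31 marker lists (lines of the grid); black dots mark medians outside the 2.5 to 97.5 percentiles of 10000 expression-matched random lists. EpCAM and CD11b have opposite colours for erythroid (−3.26 and 3.27), adipocyte (−1.51 and 1.53) and fibroblast genes (−1.24 and 1.47).

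RNA alone parted the tumour into 5 regions by k-means. The largest, 678 spots (34.3%), led with Slpi (1.18), Enpp2 (1.18) and Csn1s1 (1.16) over the rest of the section and had PyMT at 120 CPM (exact Poisson 95% interval 112 to 128). A region of 388 spots led with Tesc (2.38), Car6 (2.31) and Scgb1b27 (2.30) and had PyMT at 122 CPM (112 to 134) and the highest mean EpCAM antibody level (1.43 ± 0.234 SD across spots, natural log relative to the panel). A region of 300 spots led with Iglc1 (3.57), Cfd (2.96), Pi16 (2.91) and Jchain (2.72), with PyMT at 41.2 CPM (34.4 to 49.0), a fibroblast share of 0.420% of counts and a tumour macrophage share of 0.638%. The smallest, 133 spots, led with Hba-a2 (5.21) and the skeletal muscle genes Myh4 (4.90) and Tnnt3 (4.73), at a median of 2039 RNA counts per spot. The last, 479 spots at a median of 4058 RNA counts, had Ighg2b (1.52) and Bpifb5 (1.34) among its leading genes. Regions took up 39.2% of the variance of EpCAM antibody, 36.6% of CD11b and 26.9% of Podoplanin, and 8.46% in the median antibody. With 4 regions CD11b was at 16.7% and the median at 5.78%.

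Spleen and tumour differed in the share of RNA counts that each list took. B cell genes took 1.04% ± 0.00537 in the spleen and 0.000999% in the tumour, T cell genes 0.218% and 0.00355%, class II presentation 1.45% and 0.231%, and erythroid genes 4.95% ± 0.157 and 0.0405%. The erythroid ratio was 122-fold, and 17.5-fold (0.155% and 0.00885%) without immunoglobulin and haemoglobin genes. Milk proteins took 1.39% in the tumour and 0.00106% in the spleen, luminal epithelium 0.524% and 0.00171%, fibroblast and matrix 0.292% and 0.0605%, and hypoxia and glycolysis 0.369% and 0.0671%. The plasma cell list took 2.54% ± 0.113 in the spleen, 11.5 times the 0.221% of the tumour, but 0.435 times the tumour share once immunoglobulin and haemoglobin genes were left out, genes that took 7.70% and 0.111% of counts. Of 31 lists 19 were higher in the spleen. Tissue, strain and sequencing instrument all differed between spleen and tumour and cannot be told apart.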

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

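Marker lists were compared between tissues for 146 pairs of an antibody and a list, and the pairs below are those whose medians went opposite ways in both spleen sections and in the tumour; the least size (0.3 in log2) and number of members (5) for this were chosen after the tumour values were seen. Neither difference was tested, since the tumour is a single section. Antibody levels were relative to panels of 21 antibodies in the spleen and 32 in the tumour, so a high level is not the same measure in both. They also varied less in the tumour. The SD across spots was 0.399 and 0.449 in the spleen sections and 0.128 in the tumour for CD4. For F4/80 it was 0.601 and 0.656, and 0.119.

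Erythroid genes went down with CD4 antibody in the spleen and up with it in the tumour. Between the 25% of spots with the most and the 25% with the least CD4 antibody, the median log2 ratio of 11 erythroid genes was −0.94 and −1.01 in the spleen sections, and that of 7 measured genes was 1.02 in the tumour, above all random lists, a difference of 2.00. Hba-a2 was at 1.33 and Hbb-bs at 1.07 in the tumour, where the RNA of Cd4 itself gave 13 and 9 counts. The CD4-high tumour spots had a median of 11497 RNA counts against 5388.5 in CD4-low spots.

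T cell genes went down with F4/80 antibody in the spleen and up with it in the tumour. The median log2 ratio of 16 T cell genes between the same shares of spots by F4/80 antibody was −0.33 and −0.32 in the spleen sections, and that of 14 genes was 0.41 in the tumour, a difference of 0.734. Trbc2, a T cell receptor constant chain, was at 1.34 (95% interval 0.58 to 2.14) and Cd3e at 0.44 in the tumour. The tumour median lay at the 96.9 percentile of random lists, within their 2.5 to 97.5 range.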

How the results depend on the processing

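All alternatives were planned, and the number of tests is limited by 2 spleen sections and 1 tumour section. Without the section block, B against T gave 49 genes in place of 512 and macrophage against B and T gave 409 in place of 2019, and the median count per single antibody was 103 in place of 592; without the block the spread between sections enters the error, and no gene called in both had the opposite sign. DESeq2 gave 96 and 421 genes, out of 5700 and 9724 with an adjusted p-value in place of 13290, and the cause was not tested. With an estimated correlation 2 lists passed in B against T and 1 in the macrophage comparison, 3 in all in place of 30. In B against T the estimate was −0.0508 for T cell, −0.00315 for B cell and −0.0964 for T zone stroma genes. These lie below the preset 0.01, yet the adjusted camera p-values rose, for T cell genes from 3.8e-112 to 0.0346. A higher correlation thus cannot account for the rise in these lists. In others, such as dendritic cell genes (0.169), the estimate was above the preset. The 2 settings also differ in degrees of freedom. Camera with an estimated correlation uses the 2 residual ones of the fit, and with the preset nearly as many as there are genes. List p-values with an estimated correlation are thus held up by the 2 sections as well. How much each part added was not tested. Thinning every spot moved the median spleen correlation to 0.0425 and the own genes in the top 1% to 2. It left 17 of 19 antibodies with a value, fewer counts and spots (2560 and 2484), and equal depth, and the cause was not tested. Levels centred across spots moved the tumour median to 0.176. Such levels rank spots as raw counts do, so the spots' total antibody counts stay in. In the tumour these totals followed total RNA with rho 0.598. How much of the move this made was not tested. A class lead of 0.5 SD moved the class match to 87.4%, which leaves out spots near a boundary. The median share of antibody variance between tumour regions was 5.78% with 4 regions, 10.2% with 6, and 8.17% with counts per 10000, where the cause was not tested.

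The values that reversed were Igkc (0.10, adjusted p = 2.6e-06) and Igha (0.067, adjusted p = 0.0123) in B against T with k-means antibody classes, where the main values of 0.00 and −0.04 did not pass and the cause was not tested, and the spleen share of the plasma cell list over that of the tumour, 0.435 once immunoglobulin genes, which are members of it, were left out. Leaving out each section in turn gives values without a test: the median correlation ranged from 0.0622 to 0.0889, own genes in the top 1% from 8 to 9, the class match from 56.1% to 57.0%, genes with the called sign stayed at 512 and 2018, and antibodies that kept their sign at 15 in each comparison. The sign counts are no separate support, since a call in the blocked fit already rests on both sections moving alike. Among single genes, lists and antibodies, 3376 values were the same under an alternative, 300 moved, 245 lost and 25 gained their call, counted over all alternatives. Tumour correlations were judged against the spread between spleen sections and tumour ratios against their counting interval. The alternative with isotype controls was not run, since the panels hold none. Depth limits the tumour most for genes such as Itgam (26 and 8 counts) and Cd4 (13 and 9 counts).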

Other observations

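The tests of Ly6G and EpCAM antibodies in the spleen were chosen after the result was seen, as was the rule that a value must clear its bound by over 1 SD between sections; the other tests below were set before their values were seen, on patterns noticed in the data. Further groups moved with single antibodies in the spleen. The values are means ± SD of the list medians of 2 sections, as log2 ratios of the 25% of spots with the most over the 25% with the least antibody. Counts of members past the test are given with the section as a block, adjusted over the list alone, and without the block. CD169-high spots had more marginal zone macrophage genes (0.53 ± 0.0286, 4 of 6 members, 4 and 4) and fewer erythroid genes (−0.76 ± 0.0837, 11 of 11, 11 and 10). CD38-high spots had more B cell genes (0.26 ± 0.0133, 13 of 13, 13 and 2) and fewer T cell genes (−0.39 ± 0.0281, 15 of 16, 15 and 2). CD29-high spots, by the antibody to integrin beta 1, had more erythroid genes (0.84 ± 0.0171, 11 of 11, 11 and 10), led by Hbb-bt (1.13), and more red pulp macrophage (0.39, 11 of 12, 11 and 7), megakaryocyte (0.83 ± 0.0967, 6 of 7, 6 and 5) and endothelial genes (0.33 ± 0.0395, 6 of 10, 9 and 1), although Itgb1 RNA did not follow the antibody. IgM-high spots had more plasma cell genes (0.16 ± 0.00504, 5 of 11, 6 and 1). CD8-high spots had fewer marginal zone macrophage genes (−0.30, 3 of 6, 5 and 1), such as Marco (−0.43), and MAdCAM1-high spots had more follicle stroma genes (0.16 ± 0.0516, 4 of 8, with 5 higher and 1 lower over the list alone and 0 without the block). Most members counted for CD38, IgM, MAdCAM1, CD8 and, among endothelial genes, CD29 thus passed only with the block.

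In the tumour, Podoplanin-high spots had more Pdpn RNA (1.5, 95% interval 1.25 to 1.76) and Ly6A/E-high spots more Ly6a (1.17, 1.04 to 1.29). The region led by Slpi had the highest mean levels of both antibodies (1.94 and 1.64, natural log relative to the panel) and a smooth muscle share of 0.299% of counts, with 0.295% in the region led by Iglc1 and 0.110% in that led by Tesc. The region led by Tesc had the highest luminal epithelium share, 0.638%, and cell cycle share, 0.107%. The neutrophil list took 0.629% of tumour counts against 0.0167% in the spleen, mainly from Lcn2 at 5712 and 6187 CPM in EpCAM-high and EpCAM-low spots, a gene that epithelia also express, while S100a8 gave 7 and 19 counts there.

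F4/80 antibody followed Hba-a2 RNA across spleen spots with rho = 0.838 ± 0.0149. Uneven depth is argued against, since the value was 0.823 in spots thinned to equal counts. A few abundant genes taking most of the counts is argued against as well, since F4/80 followed the erythroid genes other than globins with 0.573. Antibodies that stay in the red pulp without their target may add to it and cannot be told apart from binding to macrophages among red cells: Ly6G and EpCAM, whose genes were counted in 0.493% and 5.12% of spleen spots, had a mean rho with Hba-a2 of 0.0774 ± 0.0733. That spread keeps it open, and EpCAM is a weak control, since Epcam was not absent. A place where F4/80 macrophages and red cells lie together stays a hypothesis, which was not tested further.

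Tumour antibodies rose and fell together in raw counts, with a median pair rho of 0.948. Deeper counting is argued against as the whole cause, since the value was 0.799 when counts were thinned to the median spot total of the spleen. Total RNA per spot is argued against as the whole cause too, since the median pair rho was 0.931 at fixed total RNA. Total antibody counts followed total RNA with rho 0.598 only, so little could be taken out this way. Neither test evens out the spots' total antibody counts. Unbound or unspecific tags could still be a source, which was not tested because the panel holds no isotype controls, and whether tumour counts are unique molecules is not given in the sources used here. No biological explanation was tested.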
